A study of Mus musculus with 80 samples.

How the data were processed

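The series holds CUT&Tag libraries, in which an antibody-guided transposase cuts and tags DNA beside a histone mark, from mouse cells on the way from embryonic fibroblasts (MEFs) to chemically induced pluripotent stem cells (iPSCs). The labels name 80 libraries, 2 for each of 5 marks (H3K4me3, H3K27ac, the lactylation mark H3K18la, H3K27me3 and H3K9me3) at each of 8 stages: D0 (MEF), D2, D4, D6, D8, D10, D12 and iPSC. The MEFs came from embryos with the OG2 transgene, and the iPSCs were kept on feeder cells of a kind not given, in a medium with N2 and B27 supplements, LIF, CHIR99021 and PD0325901, per the labels' protocols. Libraries were grouped by the mark and stage in their titles.

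The deposited files are 40 peak lists, 1 per mark and stage, in the 10-column layout of MACS2. fastp 0.20.1, Bowtie2 2.2.5, MACS2 2.1.2 and deepTools 3.4.3 were used on the mm10 build, per the submitters' processing notes. Whether the 2 libraries of a stage were pooled before calling, and whether a control library was used, is not given in the sources used here. The peak names of the H3K18la list of D2 carry a library number, so that list may hold 1 library. Each deposited peak has the authors' fold enrichment, a ratio of the pileup at the summit to the local background, and the authors' −log10 p-value and −log10 q-value. Every listed peak had a p-value of at most 1e-05. These values belong to single peaks and were used only to rank or filter peaks within a list.

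Peaks on chromosomes 1 to 19, X and Y were used. The other 3092 of 713652 peaks, on unplaced and unlocalised sequences and the mitochondrial genome, were left out and counted. Read totals are not part of the lists, so depth was taken from the peaks themselves. The whole-number pileup and the background behind each peak were solved from its fold enrichment and p-value under the Poisson model of the caller, which succeeded within 0.01 on the −log10 scale for 100.0% of the peaks tested, and the most common background of a list was taken as its genome-wide depth. It lay between 1.31 and 4.06 fragments per position. On 5000 peaks simulated with the same formula the pileups were recovered exactly in 100.0%, which checks the solving step and not the depth of the deposited lists. In those lists the most common background was that of 3.46% (H3K27me3 at D2) to 27.7% (H3K4me3 at D2) of the solved peaks.

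Similarity of lists was the Jaccard index of covered bp. Its relation to day was tested with two-sided exact permutation tests of Pearson's r and Spearman's rho over D2 to D12 (against D0) and over D0 to D12 (against iPSC), a family of 10 relations per statistic adjusted by Benjamini-Hochberg. Peaks overlapped when they shared at least 1 bp. MEF-specific peaks were D0 peaks with no overlapping iPSC peak, and iPSC-specific peaks the reverse. Intermediate-only regions had a peak in at least 3 consecutive stages from D2 to D12 and none in D0 or iPSC. Co-occupancy was set beside the mean over 100 random placements of the peaks on their chromosomes. Shares have 95% intervals (Wilson for peaks, exact Clopper-Pearson for gene lists), which cover counting error only, since neighbouring peaks are not independent.

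Genes were the 21887 protein-coding genes with 1 position in the RefSeq table of GRCm38.p6, whose chromosome coordinates are those of mm10. That table gives gene bounds without strand or transcript starts, so the planned promoter window could not be built. It was replaced, once the table had been opened and before the gene lists were counted, by a window of 1.0 kb either side of a gene end. Where H3K4me3 in any of the 8 lists marked only 1 end (12329 genes), that end was used, and otherwise both (2355 genes with both ends marked and 7203 with none). A gene whose annotated bounds lie away from its active start can therefore lack a gene-end peak, as Esrrb, Nr5a2, Pdgfra and Prrx1 did for H3K4me3 at every stage.

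For each of 25 gene lists fixed before the data were examined, the members with a gene-end peak were counted at each stage. Net change was the number of members with a peak only in iPSC less the number with a peak only in D0. Its percentile came from 10000 random lists drawn from the genes with a peak of that mark at any stage, each as long as the number of list members with such a peak. A percentile of 0 means that no random list had a net change as low. It describes these lists and is not a p-value. On simulated lists of 25 independently drawn genes without a planted change, 5.75% fell outside the central 95%. The gene families (zinc finger, protocadherin, olfactory and vomeronasal genes) hold near-identical copies, so their peaks depend on how repeated reads were placed. Of the listed names, 2 (Zscan4e and Dux) had no match.

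Besides list members, the text names genes by a rule fixed beforehand: per mark, the 10 genes with the highest authors' fold enrichment in iPSC among genes without a D0 peak, the 10 highest in D0 among genes without an iPSC peak, and the 5 highest among genes with a peak in at least 3 consecutive intermediate stages and in neither end. Genes without an official symbol (names of the Gm or Rik kind) counted in these ranks and were left unnamed. Alternatives fixed beforehand were the stricter part of each list (the 50% most significant peaks), lists shortened to the length of the shortest list of the mark, 50% coverage as overlap, the share of reference peaks in place of the Jaccard index, leaving out the 2 outer days, a 2.5 kb window, all genes as background, and leaving out X and Y. Both gene ends, the whole gene body, leaving out the H3K18la list of D2 or the iPSC lists, covered bp as the measure of list size, and the stricter and equal-length lists for X were added after the data were seen. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Overlaps were checked against bedtools 2.31.1 on simulated intervals.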

Results

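CUT&Tag peak lists of 5 histone marks followed MEFs through 12 days of chemical reprogramming, sampled every 2 days, and in the resulting iPSCs. There was 1 deposited list per mark and stage, 40 in all, so no value below has a replicate spread. Differences between stages are differences between lists, and the only tests are correlations over lists, with day or with depth. H3K4me3 marks active and poised promoters, H3K27ac active promoters and enhancers, H3K27me3 Polycomb-repressed genes and H3K9me3 heterochromatin, while H3K18la is a lactate-derived mark. The lists held from 7009 peaks (H3K18la at D2) to 37784 peaks (H3K27ac at D0). Depth, read as the genome-wide background of each list, ran from 1.31 (H3K18la at D2) to 4.06 fragments per position.

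The first question was how the genes of the starting and final cell identity were marked. Of 25 pluripotency genes, 9 carried an H3K4me3 peak at a gene end at D0 (36.0%, 95% CI 17.97 to 57.5) and 22 in iPSCs (88.0%, 68.8 to 97.45). The counts in between were 12, 13, 12, 15, 18 and 19 from D2 to D12. Klf4, Sox2, Sall4 and Tbx3, transcription factors of the pluripotency network, had H3K4me3 at all 8 stages. Zfp42, Nr0b1, Dppa5a and Pou5f1 first had it at D10, and Dppa2, which acts in early embryonic chromatin, at D12. Nanog (chromosome 6, 122707489 to 122714633, mm10), Dppa4 and Tcl1 had an H3K4me3 peak in the iPSC list alone. H3K27ac was called at 5 of the 25 genes at D0, 14 at D12 and 15 in iPSCs, with Sox2, Zfp42 and Tcl1 first marked at D12.

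H3K27me3 was withdrawn from the same list. It was called at 14 of the 25 genes at D0 (56.0%, 34.9 to 75.6), at 15, 13, 8, 9, 7 and 1 from D2 to D12 and at 0 in iPSCs (upper bound 13.7%). The last stage with H3K27me3 was D6 for Nanog, D10 for Sox2, Fgf4, Prdm14 and Pou5f1, and D12 for Utf1. Against random lists, the net changes lay at percentile 100.0 for H3K4me3 and H3K27ac and at 0 for H3K27me3. Pou5f1 (chromosome 17, 35506032 to 35510777) also had an H3K9me3 peak in every list from D0 to D12. Peaks around Pou5f1 had a median local background of 16.98 times the genome-wide one, against 2.79 times in the flanking 1.0 Mb, and the background was above that of the flanks in each of the 34 lists with a peak there. It differed with mark and stage, from 4.38 (H3K27me3 at D12) to 123.9 (H3K4me3 in iPSCs). With lists of equal length the H3K4me3 net gain was 8 genes in place of 13.

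The fibroblast and mesenchyme genes moved the other way. H3K27ac was called at 21 of 25 at D0 (84.0%, 63.9 to 95.5), at 17, 14, 13, 9, 7 and 6 from D2 to D12, and at 2 in iPSCs, Fn1 and Zeb1. Col1a1 (chromosome 11, 94936224 to 94953042), the main fibrillar collagen gene, last had H3K27ac at D2, Thy1 and S100a4 at D6, and Twist1, an inducer of mesenchymal identity, at D12. H3K4me3 stayed longer: 21 genes had it at D0, 20 at D10, 15 at D12 and 12 in iPSCs. Col6a1, Dcn and Acta2 had H3K4me3 up to D10, and Col1a1, Pdgfrb, Snai1 and Zeb2 up to D12. H3K27me3 was called at 5 genes at D0 and 9 in iPSCs (percentile 98.4), among them Twist1 and Snai2 from D10 on. In the stricter part of each list the H3K4me3 net change turned to a gain of 3 genes. The H3K27ac percentile, 0.005, was 3.02 in the stricter part and 4.07 at equal length, and the iPSCs were grown on feeder cells of a kind not given, per the labels' protocols.

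**Figure D1:**
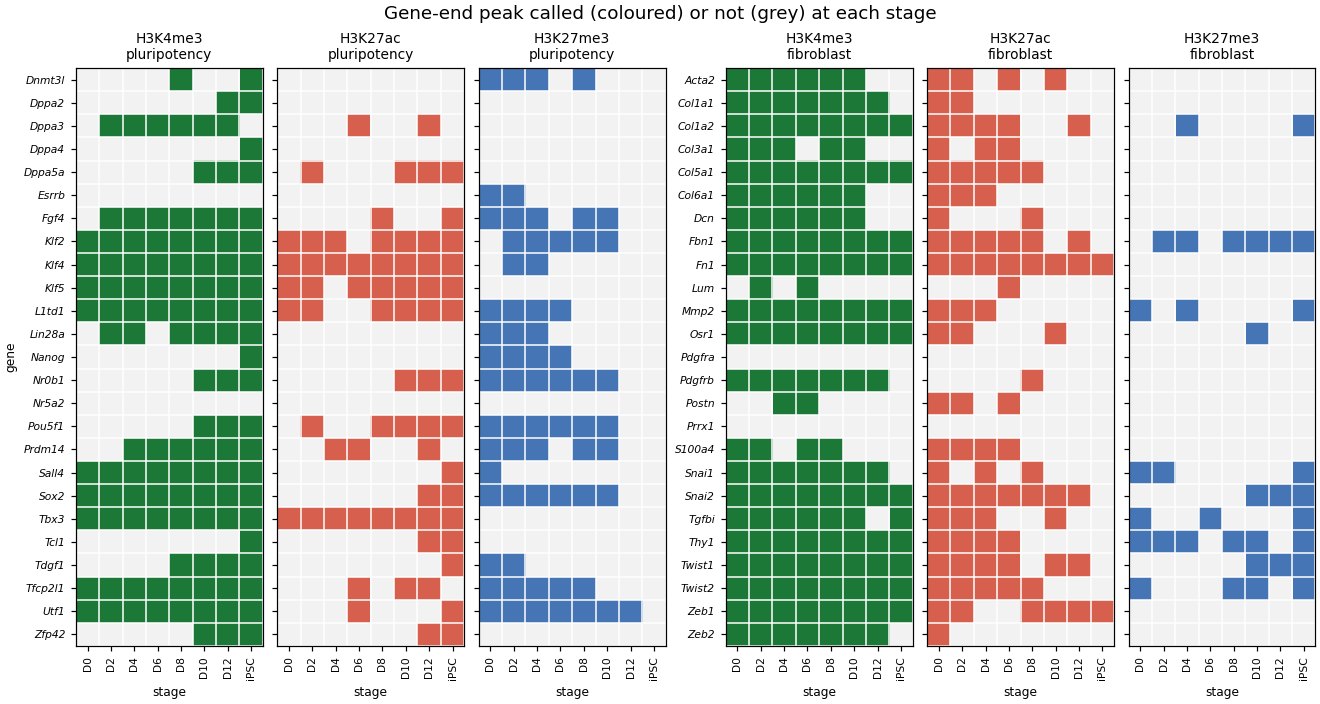
Gene-end peaks of H3K4me3, H3K27ac and H3K27me3 at 25 pluripotency genes (left panels) and 25 fibroblast and mesenchyme genes (right panels), rows being genes and columns the 8 stages. A coloured cell means that the deposited list holds a peak there and a grey cell that it does not; pluripotency genes with H3K27me3 went from 14 at D0 to 0 in iPSCs, and fibroblast genes with H3K27ac from 21 to 2.

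Epithelial genes with a called H3K27ac peak were most numerous from D8 to D12 and few in iPSCs. Of 18 such genes, 4 had H3K27ac at D0, 5 at each of D2, D4 and D6, 10 at D8, 15 at D10, 13 at D12 and 2 in iPSCs, Cdh1 and Spint2. Epcam (chromosome 17, 87635979 to 87651127), Grhl2, Esrp1, Ocln and keratins Krt8, Krt18 and Krt19 were among the 12 genes with H3K27ac only between D2 and D12. Cdh1, the E-cadherin gene of cell adhesion, had it from D2 on. H3K27me3 covered 17 of the 18 genes at D0, 13 at D6, 5 at D8, 4 at D10 and 9 in iPSCs, where it was again called at Epcam, Krt19, Ocln and Dsp. The D12 net gain of H3K27ac (9 genes) was at percentile 100.0, and the loss of 11 genes from D12 to iPSC at percentile 0.78 of that step. Among all genes, those with an H3K27ac gene-end peak numbered 11227 at D12 and 6535 in iPSCs. The net change from D0 to iPSC was -2, at percentile 97.7 of random lists, whose median was -7. The step from D12 to iPSC was not repeated in the stricter part or at equal length.

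Of 13 genes of primitive endoderm, an extraembryonic lineage, H3K27ac was called at 6 at D0, then at 5, 7, 4, 4, 7 and 8, and at 1 in iPSCs, Lama1. The D12 net gain of 2 lay at percentile 95.6, inside the central 95% of random lists. H3K4me3 was at 6 of the 13 at D0, 11 at D12 (percentile 99.975) and 9 in iPSCs. Gata4 and Hnf4a, endoderm transcription factors, had both H3K4me3 and H3K27ac at D10 and D12 and at no other stage, and Sox17 had H3K27ac from D4 to D12. The step from D12 to iPSC (net loss of 7) lay at percentile 1.72. Formative and primed genes had H3K4me3 at 8 of 13 at D0, 8 at D12 and 11 in iPSCs, with Otx2 and Lefty1 in the iPSC list alone, and H3K27me3 at 10, 2 and 3. None of 9 genes of the 2-cell-like list had an H3K4me3 or H3K27ac peak at any stage. Its members Zscan4e and Dux had no match, and read placement among its Zscan4 genes was not examined. The missing peaks therefore do not show that these genes were unmarked.

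**Figure D2:**
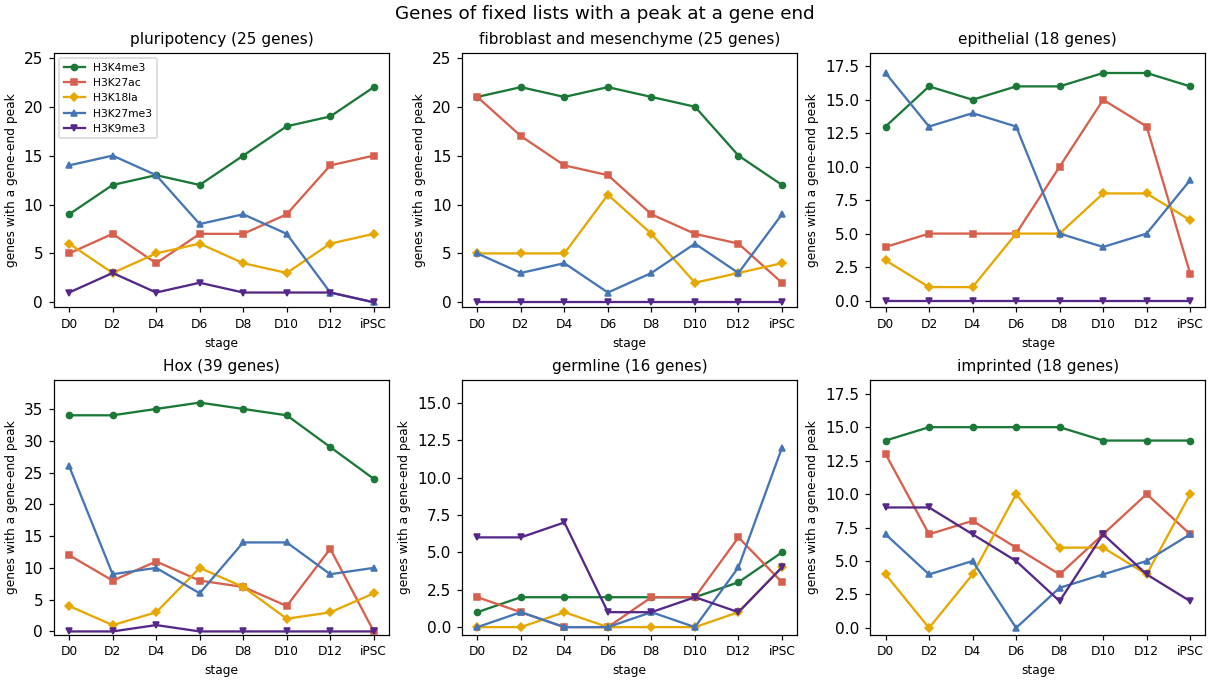
Number of genes with a gene-end peak (y axis) at each of 8 stages (x axis) for 6 fixed lists, a line per mark, each point from 1 list. Epithelial H3K27ac stood at 15 of 18 genes at D10 and 2 in iPSCs, and germline H3K27me3 at 0 of 16 at D0 and 12 in iPSCs.

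Developmental regulators had fewer H3K27me3 peaks at each later stage than at D0, without a steady decline. H3K27me3 was called at 26 of 39 Hox genes at D0 (66.7%, 49.8 to 80.9), at 9, 10, 6, 14, 14 and 9 from D2 to D12 and at 10 in iPSCs (25.6%, 13.04 to 42.1). Hoxb1, Hoxd1 and Hoxd12 had it at all 8 stages. Of 32 lineage regulators, 27 had it at D0, 21, 14, 10, 12, 19 and 10 from D2 to D12 and 16 in iPSCs, the D6 list being the shortest of the mark. Neurog1, Sim1, Mixl1 and Olig1 were marked throughout, while Hand2, Lhx2 and Olig2 had it at D0 alone. H3K4me3 at Hox genes was called at 34 at D0, 29 at D12 and 24 in iPSCs, being absent there from Hoxa3, Hoxb7, Hoxb8 and Hoxc4. H3K27ac was at 12 Hox genes at D0, 13 at D12 and 0 in iPSCs, a net loss at percentile 19.8 of random lists, whose median net change was -10. The Hox H3K4me3 net change of iPSC against D0 was -10 (percentile 0), 6 in the stricter part of the lists (88.1), -27 at equal length, and -2 with a 2.5 kb window (2.56) and over gene bodies (1.22). That of H3K27ac was -12, -1 in the stricter part (percentile 99.5) and at equal length (98.2), -21 with a 2.5 kb window (0.095) and -20 over gene bodies (0.01), so its side of the central 95% depends on these settings. The D0 list was the longest of H3K27me3, and at equal length the Hox net loss of 16 was 7. The lineage regulators' H3K27me3 net change of -11 was -6 with a 2.5 kb window and -5 over gene bodies.

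Genes with gene-end peaks of both H3K4me3 and H3K27me3, called bivalent here, numbered 3394 at D0, 2452 at D2, 3225 at D4, 1654 at D6, 2087 at D8, 2898 at D10, 1738 at D12 and 3475 in iPSCs. The peaks of both marks need not overlap, can lie at opposite ends of a gene, and may come from different cells. Of the genes bivalent at D0, 59.8% (58.2 to 61.4) were bivalent in iPSCs, 35.3% (33.7 to 36.9) had H3K4me3 alone, 3.15% H3K27me3 alone and 1.74% neither. Epcam, Mixl1, Neurog1 and Sim1 were bivalent at both ends, and Tfcp2l1, Sox2 and Utf1 went from both marks to H3K4me3 alone. The H3K27me3 list of D6 was the shortest of that mark, with 7574 peaks, and at equal length the iPSC count was 1830. The stricter part of the lists gave 895 bivalent genes at D0 and 1783 in iPSCs.

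Germline genes, several of which act in meiosis, were the reverse case for H3K27me3. None of 16 had it at D0 (upper bound 20.6%), 4 had it at D12 (Sycp1, Sycp3, Hormad1 and Slc25a31) and 12 in iPSCs (95% CI 47.6 to 92.7%), adding Dazl, Ddx4, Mael, Tdrd1 and Taf7l among others. H3K9me3 was called at 6 of them at D0, 7 at D4, 1 at D6 and 4 in iPSCs. Other marks were also gained at germline genes, with H3K4me3 at 1 at D0 and 5 in iPSCs (percentile 99.995) and H3K18la at 0 and 4 (99.99). H3K27ac was called at 2 at D0, 6 at D12 and 3 in iPSCs. Its net change of 1 from D0 to iPSC lay at percentile 99.3 of random lists, whose median was -3. Clustered protocadherins, cell adhesion genes, had H3K27me3 at 2 of 39 at D0 and 20 in iPSCs, and H3K4me3 at 4 and 13. Net changes of H3K27me3 were at percentile 100.0 for both lists. With lists of equal length the germline net gain was 7 genes, and with a 2.5 kb window that of the protocadherins was 34.

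H3K9me3 at gene ends was sparse, with 300 genes at D0 and 613 in iPSCs. Imprinted genes had it at 9 of 18 at D0, 4 at D12 and 2 in iPSCs (Igf2 and Impact), while Zrsr1 had it up to D12 and Plagl1 up to D10. H3K18la at the imprinted genes was called at 4 at D0 and 10 in iPSCs, including Mest, Impact and Peg10 (percentile 99.99). Olfactory receptor genes had H3K9me3 at 19 of 1110 at D0, 25 at D2 and 5 in iPSCs, vomeronasal receptor genes at 6 of 355 at D0 and 6 in iPSCs, and zinc finger genes at 20 of 397 and 41. The imprinted net loss of 7 H3K9me3 genes was 2 in the stricter part of the lists and at equal length. The olfactory net loss of 14 was 7 and 5 there, and over gene bodies its percentile went from 0 to 16.3.

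H3K18la was examined for the genes and marks it accompanied. Glycolysis and lactate genes had it at 11 of 21 at D0, then at 9, 13, 16, 16, 10 and 11, and at 9 in iPSCs. Eno1, Pfkl and Pkm, enzymes of glycolysis, had it at all 8 stages, Pgk1 and Aldoa at D6, D8 and D10 alone, and Tpi1 at D6 and D8. The net gain of 5 genes from D0 to D6 was at percentile 88.7 and that to D8 at 97.2. Genes of senescence and cell cycle arrest had H3K18la at 3 of 10 at D0 and 8 at D4 and at D6 (percentiles 99.95 and 99.5). The count was 4 at D8 and D10, 5 at D12 and 4 in iPSCs (percentile 85.2). Cdkn2a and Cdkn2b were marked at each stage from D2 to D6, at D12 and in iPSCs and not at D0. In the D6 list, the longest of the mark, fibroblast genes went from 5 at D0 to 11 (percentile 97.4) and Hox genes from 4 to 10 (96.7). mTOR pathway genes had H3K18la at 11 of 12 at D0 and 7 in iPSCs (percentile 9.985). Chromatin regulators had it at 10 of 17 and 4 (percentile 1.65), and housekeeping genes at 6 of 12 and 4 (percentile 28.5).

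At D0, 75.9% (75.1 to 76.6) of H3K18la peaks overlapped H3K27ac and 65.9% (65.1 to 66.7) H3K4me3, against 2.09% and 1.5% of randomly placed peaks. In iPSCs the shares were 51.8% (51.0 to 52.6) and 75.4% (74.7 to 76.1), against 0.92% and 1.97% at random. From D2 to D12 the share with H3K27ac was 86.4%, 68.7%, 61.8%, 57.6%, 84.4% and 86.7%. The H3K18la lists of these stages held 7009, 11800, 18455, 13764, 7500 and 8616 peaks, so the higher shares came from the shorter lists. This course was not redone at equal length. With lists of equal length the share with H3K4me3 was the lower in iPSCs, at 85.5% at D0 and 76.2% in iPSCs. H3K27me3 overlapped 19.7% of H3K18la peaks at D0 and 22.9% in iPSCs. The number of H3K18la peaks followed depth over the 8 lists (Spearman rho 0.90, exact permutation p = 0.0046, adjusted p = 0.0228 over 5 marks; Pearson r 0.92, p = 8.18e-04, adjusted p = 0.0041). With covered bp in place of peak number rho was 0.71 (adjusted exact permutation p = 0.288) and r 0.90 (adjusted p = 0.0156). Without D2 and D6, the lists farthest from the median depth, r was 0.89. The Spearman correlation was 0.86 without the D2 list, which may hold 1 library, and also without the iPSC list, with adjusted exact permutation p of 0.119 and 0.0595 over 7 lists. In the other marks the number of peaks did not follow depth over the 8 lists. There rho was -0.43 for H3K4me3, 0.31 for H3K27ac, 0.26 for H3K27me3 and 0.38 for H3K9me3 (adjusted exact permutation p = 0.536 for each). H3K9me3 peaks overlapped H3K4me3 in 1.42% (1.25 to 1.60) at D0, 11.7% (11.1 to 12.4) at D12 and 19.9% (19.3 to 20.4) in iPSCs, with 1.37%, 1.60% and 1.86% at random.

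**Figure D3:**
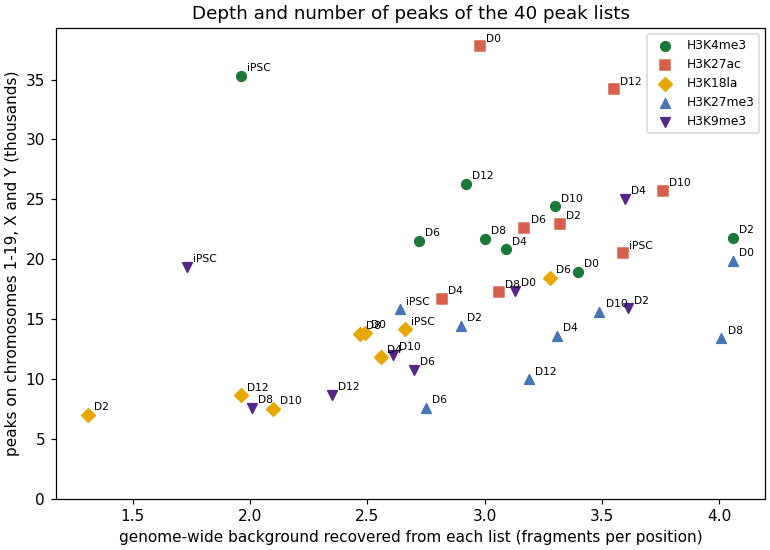
Number of peaks (y axis) against the genome-wide background recovered from each list in fragments per position (x axis), 1 point per list, coloured by mark and named by stage. H3K18la points run from 7009 peaks at a background of 1.31 (D2) to 18455 peaks at 3.28 (D6).

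Genes outside the lists were named by the highest authors' fold enrichment within a list. In the iPSC H3K4me3 list, the leading genes with an official symbol and no D0 peak were Nalcn, Fmr1nb, Spag6l and Dync2li1, at fold enrichments of 12.7, 12.5, 12.5 and 12.1, with genes lacking a symbol ranked above and between them. Spag6l and Dync2li1, both cilia genes, were marked from D2 on, and Fmr1nb from D12. Antiviral genes Ddx60, Herc6 and Ifit1bl1 were among the 10 leading D0 genes without an iPSC peak, and Ddx60 and Herc6 kept H3K4me3 up to D12. Acot4, Cftr and Dnah7c carried H3K4me3 from D2 to D12 and at neither end. For H3K27ac, Acsm3, Bmp3, Crb1 and Psma8 were among the 10 leading iPSC genes without a D0 peak, and Zfp599, Fbxl21, Zfp866 and Xpa among the 10 leading D0 genes without an iPSC peak. Pm20d1, Ikzf2 and Sytl4 were intermediate. Genes with an H3K4me3 peak in iPSCs and none at D0 numbered 1084, and those with a peak at D0 and none in iPSCs 568, whatever their state in between. For H3K27ac these numbers were 439 and 5829.

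For H3K18la the leading iPSC genes were Chgb, Atxn7l3b and Klhl9, each with a peak already at D2, the leading D0 genes Bet1, Rmdn1 and Yipf4, and the leading intermediate genes Taco1, Atp6v1h and F2r. For H3K27me3 the leading iPSC genes with a symbol were Asmt and Mid1, both on X and in the iPSC list alone at fold enrichments of 26.6 and 11.7, then Phlpp1 and Crb1. Slc22a29 led the D0 list at 26.2 and kept its peak up to D12, and Cdv3 and Armc4 led the intermediate genes. For H3K9me3, histone genes H2ac6 and H2bc4, which shared a peak, Cyp20a1 and Usp14 led the iPSC list, and Zfp959, Ddx4 and Ezhip the D0 list. Snurf, at the imprinted Snrpn locus, carried H3K9me3 from D2 to D10 and at neither end.

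Marker lists of other cell types the cultures could hold were small. H3K4me3 was called at 4 of 8 endothelial genes at D0 and 3 in iPSCs, 3 and 1 of 8 macrophage and blood genes, 5 and 6 of 8 neuronal genes, 1 and 3 of 8 skeletal muscle genes, 3 and 5 of 8 trophoblast genes and 2 and 3 of 8 hepatic genes. The blood markers lost were Spi1 and Cd68 (percentile 0.165), and the muscle markers gained Ckm and Myod1 (percentile 98.7). Over all 110 pairs of list and mark with a peak, 20 lay above the central 95% of random lists and 14 below. The nominal number outside for lists of independently drawn genes is 5.5, which short lists need not follow. Where 1 member had a peak at any stage, its loss lay at percentile 7.96 for senescence H3K9me3 and 21.0 for skeletal muscle H3K27ac. The lists share members, the marks were scored on the same genes, and Hox and protocadherin genes lie in clusters. The excess over 5.5 is therefore not a test.

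The next question was when the landscape as a whole left the MEF state and approached the iPSC state. The H3K4me3 index with D0 went from 0.714 at D2 to 0.546 at D12 (Spearman rho -1.0 and Pearson r -0.94, exact permutation p = 0.0028 for both, the smallest that 6 lists allow, adjusted p = 0.0278). Its index with iPSC went from 0.418 at D0 to 0.462 at D12 (r 0.87, p = 0.0111, adjusted p = 0.0486; rho 0.82, p = 0.0341, adjusted p = 0.114). For H3K27ac the index with D0 went from 0.358 at D2 to 0.239 at D12 (r -0.86, exact permutation p = 0.0194, adjusted p = 0.0486; rho -0.94, p = 0.0167, adjusted p = 0.0833) and that with iPSC from 0.126 at D0 to 0.194 at D12 (r 0.83, p = 0.0183, adjusted p = 0.0486; rho 0.79, p = 0.048, adjusted p = 0.12). No trend of H3K18la, H3K27me3 or H3K9me3 passed adjustment, the nearest being H3K27me3 with D0 (r -0.83, exact permutation p = 0.0472, adjusted p = 0.0944). In the stricter part of the lists no trend passed, though r of H3K4me3 with D0 was -0.96 (adjusted exact permutation p = 0.0556) and rho -0.94 (adjusted p = 0.0833). At equal length rho also passed for H3K4me3 with iPSC (0.96, adjusted exact permutation p = 0.0139) and for H3K27ac with D0 (-0.94, 0.0417) and iPSC (0.89, 0.041). Without the 2 outer days r of H3K4me3 and H3K27ac with iPSC was 0.60 and 0.61 (exact permutation p = 0.3 for both), so these trends rest on the outer days. With the share of reference peaks in place of the index, the trends of H3K4me3 with D0 and of H3K27ac did not pass either. Without X and Y, r of H3K4me3 with iPSC and of H3K27ac with D0 and iPSC had an adjusted exact permutation p = 0.0526.

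MEF-specific H3K27ac peaks, 30031 of 37784, were overlapped in 35.6% (35.1 to 36.1) at D2, 21.7% at D4, 30.9% at D6, 20.7% at D8, 21.8% at D10 and 24.2% (23.7 to 24.7) at D12. Of 3408 MEF-specific H3K4me3 peaks, 66.5% (64.9 to 68.1) were overlapped at D2 and 36.4% (34.8 to 38.0) at D12. iPSC-specific peaks were overlapped more often at the late stages for these marks: 3.00% (2.72 to 3.32) of 12653 H3K27ac peaks were overlapped at D2, 6.09% at D8, 13.7% at D10 and 28.3% (27.5 to 29.1) at D12, and for 18818 H3K4me3 peaks 8.93%, 11.6%, 16.2% and 24.8%. The lists of these stages held 22962, 17229, 25729 and 34185 H3K27ac peaks, and 21804, 21721, 24416 and 26290 H3K4me3 peaks. They thus grew from D8 to D12, though those of D2 were longer than those of D8. Only the D12 shares were redone at equal length, so how much of the rise follows list length stays open. At D12 the MEF-specific and iPSC-specific shares were 17.2% and 10.6% for H3K18la, 6.80% and 13.6% for H3K27me3, and 12.3% and 13.3% for H3K9me3. Intermediate-only regions numbered 1833 for H3K4me3, 1467 for H3K27ac, 1103 for H3K18la, 698 for H3K27me3 and 666 for H3K9me3. The stricter part of the lists gave 82.2% for MEF-specific H3K4me3 at D12 and 407 intermediate-only H3K4me3 regions. At equal length the D12 shares were 34.8% and 19.1% for H3K18la, 13.98% and 20.5% for H3K27me3, and 27.03% and 21.6% for H3K9me3, whose order turned there and in the stricter part (14.1% and 11.9%). The order of H3K27ac turned in the same settings, to 32.0% and 19.7% at equal length and 33.9% and 25.9% in the stricter part.

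**Figure D4:**
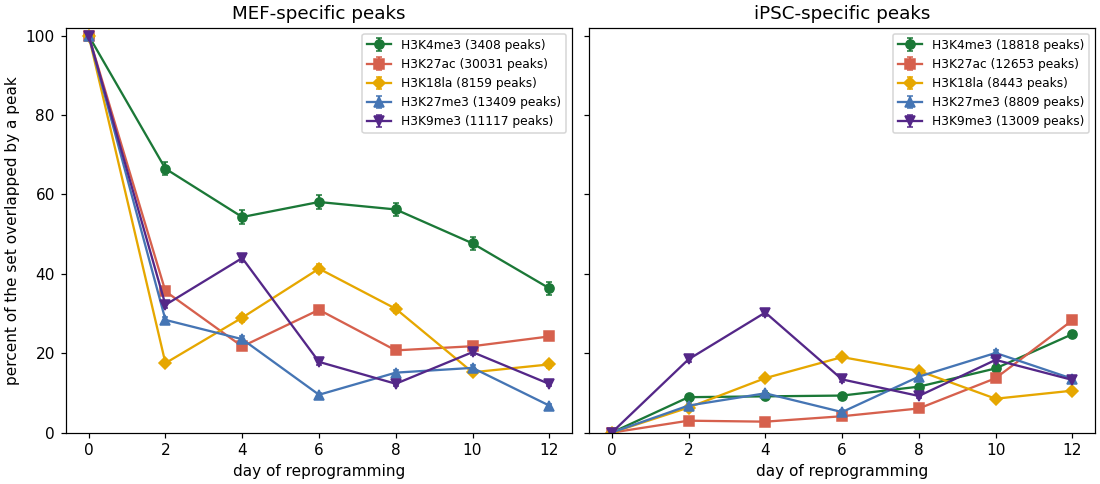
Percent of MEF-specific (left) and iPSC-specific (right) peaks overlapped by a peak of the same mark (y axis) on each day of reprogramming (x axis), by mark, with set sizes in the key and bars for 95% Wilson intervals. MEF-specific H3K4me3 stood at 66.5% on day 2 and 36.4% on day 12, and iPSC-specific H3K27ac at 3.00% and 28.3%.

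On X, H3K27me3 held 1.28% of its covered bp at D0, 1.31% at D12 and 2.05% in iPSCs, and 1.29% (1.14 to 1.45) against 2.17% (1.95 to 2.41) of its peaks at D0 and in iPSCs. H3K9me3 on Y held 0.591% of covered bp at D0 and 1.51% in iPSCs.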

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

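The tests of a longer iPSC list, of a general gain, of germline feeder signal of either kind, of open promoters and of regions shared by all marks were chosen after the results were seen; the ratio of list lengths was added when the equal-length test of the germline genes, written beforehand, had decided nothing.

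Peaks outside chromosomes 1 to 19, X and Y, which no comparison used, were a larger share of some late lists than of the D0 list of the same mark, with intervals that did not overlap. For H3K27me3 they made up 0.0453% at D0, 0.449% at D12 and 0.704% in iPSCs. For H3K27ac the shares were 0.0661%, 0.184% and 0.539%. For H3K18la they were 0.432%, 0.817% and 0.786%. For H3K9me3 the share was 1.24% at D0 and 2.09% at D12, but 0.860% in iPSCs (0.736 to 1.00), below D0. Only D12 and iPSC were compared with D0 here, and no explanation was tested.

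Germline genes with H3K27me3 went from 0 of 16 at D0 to 12 in iPSCs. List length was first tested with lists of equal length (7574 peaks): a net gain of at most 6 genes would have fitted it and a gain above 9 argued against it. The net gain was 7, between these bounds, so how much of the gain depends on list length stays open. Against D0, a longer iPSC list as such is argued against, since that list held 0.797 times the peaks of the D0 list. A general gain of the mark from D0 is argued against by the number of all genes with an H3K27me3 gene-end peak, 4647 at D0 and 4206 in iPSCs (0.905 times). From D12 to iPSC, where the germline net gain was 8 genes (percentile 98.98), both stay open. The list went there from 9972 to 15805 peaks, and all genes with a peak from 2219 to 4206. Feeder cells marked like the D0 fibroblasts would bring few such peaks. At most 20.6% of the germline genes (upper bound of 0 of 16) had the mark at D0, below the lower bound of 47.6% in iPSCs. Both bounds come from the counts that make up the pattern, so the comparison restates it and gives no separate support. Feeder cells of another kind stay open, as the kind is not given. Of the 12 genes, 4 (33.3%) already had the mark at D12, before the only stage for which the labels name feeders. This net gain of 4 from D0 to D12 lay at percentile 99.985 of random lists, whose median was -4. The interval of 4 of 16 (7.27 to 52.4%) overlaps that of 0 of 16, though these intervals ignore that the same genes were counted at both stages. The change of cell state and the change to the iPSC medium, with CHIR99021 and PD0325901, stay open as biological explanations. They were not tested, and these lists cannot separate them.

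H3K9me3 peaks overlapped H3K4me3 more often in iPSCs (19.9%) than at D0 (1.42%). Tagging at open promoters at gene ends in the H3K9me3 libraries is argued against as the main source of the overlap. H3K4me3 peaks at gene ends overlapped H3K9me3 0.230 times as often as other H3K4me3 peaks (3.50%, 3.20 to 3.82, against 15.2%, 14.7 to 15.7). A smaller part from promoters stays open, as iPSC H3K4me3 peaks placed at random overlapped H3K9me3 in 1.01%. Both ends of every gene counted as gene ends here, so promoters were not set apart. Regions that attract peaks of every mark, and open chromatin away from gene ends, stay open. Of the overlapping H3K9me3 peaks 12.7% (11.7 to 13.8) also overlapped all of the other 3 marks, against 0.484% of the other H3K9me3 peaks. Each mark was met more often by the overlapping peaks: H3K27ac by 60.6% against 2.37%, H3K18la by 45.4% against 1.77% and H3K27me3 by 22.5% against 1.26%. A mixture with fibroblast-like cells such as feeders stays open: the overlapping peaks had a D0 H3K9me3 peak in 50.6% (49.0 to 52.2) and the remaining iPSC H3K9me3 peaks in 28.4% (27.7 to 29.1), 1.78 times as often. The share was already 11.7% at D12, before the stage grown on feeders. Both marks on the same DNA in iPSCs is the untested biological alternative, and repeats were not analysed here.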

How the results depend on the processing

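No paired analysis was possible because each mark and stage has 1 deposited list, so the library numbers in the labels have no values. The planned use of the most upstream transcript start alone was not run, as the gene table gives no starts. Both gene ends, the gene body, the tests without a list, covered bp for depth and the X shares under other lists were chosen after seeing the data. Of 513 values under alternatives, 379 kept their side or stayed within their interval or 1.5 times the main count, 109 moved, 20 lost and 3 gained a pass, and 2 reversed. Of 96 net changes of lists, 94 kept their direction and 75 stayed within 1.5 times, and 98 of 112 percentiles kept their side. Using both gene ends moved none of 47 values. H3K4me3 counts could not change there, since only ends without H3K4me3 in any list had been left out. Genes with both or no ends marked kept the same ends for every mark. Where no reason is given the cause was not tested. Depth limits what a missing peak means: a gene without a called peak may still carry the mark below detection, most of all in the H3K18la list of D2, where leaving that list out gave rho 0.857 for peak number and depth.

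Trends. In the stricter part, H3K4me3 with D0 had r -0.96 and rho -0.94 and with iPSC r 0.81, and H3K27ac r -0.66 and 0.71, none passing. At equal length rho passed for H3K4me3 with iPSC (0.96, adjusted exact permutation p = 0.0139) and H3K27ac with D0 (-0.94, 0.0417) and iPSC (0.89, 0.041). Without X and Y, r of H3K4me3 with iPSC (0.87) and of H3K27ac (-0.86 and 0.82) had an adjusted exact permutation p = 0.0526. With the share of reference peaks, H3K4me3 with D0 had r -0.89 and rho -0.77 and H3K27ac r -0.51 and 0.61, not passing. Without the 2 outer days r was -0.95 and 0.60 for H3K4me3 (rho -1.0 with D0) and -0.80 and 0.61 for H3K27ac, where 4 lists cannot give an exact permutation p below 0.0833, nor 5 lists below 0.0167. H3K18la depth had rho 0.857 without D2 and also 0.857 without iPSC, and 0.714 by covered bp (adjusted exact permutation p = 0.288).

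Shares overlapped at D12, MEF-specific then iPSC-specific, in the stricter part, were 82.2% and 29.1% for H3K4me3, 33.9% and 25.9% for H3K27ac, 22.7% and 11.5% for H3K18la, 7.59% and 14.7% for H3K27me3, and 14.1% and 11.9% for H3K9me3. At equal length they were 45.9% and 23.9%, 32.0% and 19.7%, 34.8% and 19.1%, 13.98% and 20.5%, and 27.03% and 21.6%. With 50% coverage they were 46.5% and 22.5%, 23.7% and 25.6% for the first 2 marks, 3.91% and 9.69% for H3K27me3, and 11.003% and 11.2% for H3K9me3. Intermediate-only regions in the stricter part numbered 407, 398, 572, 309 and 434 in the same order of marks, and 419 for H3K27me3 with 50% coverage.

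H3K18la with H3K27ac gave 84.0%, 81.8% and 71.1% at D0 (stricter, equal length, 50% coverage) and 63.0% and 46.6% in iPSCs (the last 2). With H3K4me3 it gave 69.0%, 85.5% and 64.0% at D0 and 74.5%, 76.2% and 72.3% in iPSCs, so at equal length the D0 share was the higher. H3K9me3 with H3K4me3 gave 0.910%, 2.40% and 1.17% at D0 and 18.7%, 20.5% and 18.9% in iPSCs. Bivalent genes in the stricter part numbered 895 at D0, 535 at D6 and 1783 in iPSCs, 1830 in iPSCs at equal length, and 2879 at D6 and 5347 in iPSCs over gene bodies. The share bivalent at both ends was 43.7%, 42.6%, 64.4% (2.5 kb window) and 69.7% (gene body).

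Gene lists. In the stricter part the net change of H3K4me3 reversed to 3 for fibroblast (percentile 73.6) and 6 for Hox genes (88.1), where the iPSC list kept 17666 peaks and D0 9472. The others there were -1 for Hox H3K27ac (percentile 99.5), 7 for germline H3K27me3, -2 for imprinted H3K9me3 (5.12), -7 for olfactory H3K9me3, and percentile 3.02 for fibroblast H3K27ac. At equal length they were 8 (pluripotency H3K4me3), -11 (fibroblast H3K27ac, 4.07), -27, -1 (98.2) and -7 (Hox H3K4me3, H3K27ac and H3K27me3), 7 (germline), -2 (imprinted H3K9me3, 7.87) and -5 (olfactory). With 2.5 kb they were -2 (2.56) and -21 (0.095) for Hox H3K4me3 and H3K27ac, -6 (7.62) for lineage H3K27me3 and 34 for protocadherins. Over gene bodies they were -2, -20 (0.01) and -5 (7.22), and the olfactory percentile was 16.3. X shares of H3K27me3 were 1.04% at D0 at equal length, and 1.72% and 1.69% in iPSCs in the stricter part and at equal length.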

Other observations

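The test of the Pou5f1 region was chosen after low fold enrichments with high significance had been seen there, and the genes of the first paragraphs were picked after their values were seen.

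Peaks at the polarity gene Crb1 accumulated in more than 1 mark: it was among the 10 leading iPSC genes without a D0 peak for H3K27ac (peaks at D6 and from D10 on) and for H3K27me3 (from D6 on). Dazl, a germ cell RNA-binding protein gene, had H3K9me3 up to D4, H3K4me3 from D2 to D12 and, in iPSCs, H3K27me3 without H3K4me3. Dppa3 similarly had H3K4me3 at all stages from D2 to D12 and at neither end. Trophoblast markers had H3K27ac at 0 of 8 genes at D0, 3 at D12 (Cdx2, Eomes and Ascl2) and 0 in iPSCs, the D12 net gain lying at percentile 99.8.

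H3K27me3 was called at 7 of 8 trophoblast markers at D0, 2 at D6 and 4 in iPSCs, and at 7 and 3 of 8 neuronal markers at D0 and in iPSCs. These net changes from D0 to iPSC lay at percentiles 7.845 and 3.25, inside the central 95% of random lists. Glycolysis and lactate genes had H3K27me3 at 8 of 21 at D0 and 2 in iPSCs (percentile 0.525), among them Slc2a3, Ldhb and Hk2 at D0.

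Pou5f1 had a gene-end H3K9me3 peak in every H3K9me3 list from D0 to D12. A candidate explanation is extra copies of the Pou5f1 region in the OG2 transgene, which would raise fragments of every library there. Extra copies would give a high local background in peaks of all marks across the gene and its surroundings (chromosome 17, 35497032 to 35515777, a span chosen after looking at the peaks). Over 82 peaks from 34 of the 40 lists, the local background was a median of 16.98 times the genome-wide one (quartiles 11.4 and 26.3), against 2.79 (1.87 and 4.71) over 1858 peaks in the flanking 1.0 Mb. It was above the flanks in 34 of these 34 lists, D0 lists included, while 6 lists had no peak there. But copies alone would raise every list about alike, and the ratio differed between marks and stages, going from 28.9 at D0 to 4.38 at D12 for H3K27me3, from 10.7 at D10 to 123.9 in iPSCs for H3K4me3, and from 8.63 at D4 to 53.3 in iPSCs for H3K27ac. It lay beyond a factor of 2 of the median in 5 of the 34 lists. Genome-wide, 0.281% of 114954 H3K9me3 peaks had a background at or above 16.98 times, the region's median over peaks of all marks. Peaks with the smallest p-values were left out of this count, as they were in the region and its flanks. Without a control library the local background of the caller is taken from the same data and holds the signal of the mark itself. Whether a control was used is not given, so extra copies and strong marking of the region cannot be told apart.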
